A study of Homo sapiens with 6 samples.

How the data were processed

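Stranded mRNA libraries (TruSeq) of C4-2 cells carrying Tet-O-YAP5SA, grown in RPMI-1640 with 10% fetal bovine serum, were sequenced in 2 groups of 3. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, reads were checked with FastQC 0.11.2, aligned with STAR 2.5.3a to hg19 and assigned to genes with featureCounts. edgeR is also named there, with no role given. The deposited table gives 1 value per gene and library in TPM (reads divided by gene length and scaled to a fixed total), made by the authors, with GENCODE gene identifiers and symbols. The annotation release and the strand setting of the counting are not given in the sources used here. Each library sums to the same total over the 26819 listed genes, so a strongly induced gene lowers the share of all others, and values are relative within a library. Symbols are printed as the table gives them, with newer names in brackets, and 222 listed genes repeat the symbol of a gene listed earlier. Positions are not given, because the reads were aligned to hg19 and the annotation used here is that of GRCh38 (GENCODE 29), which served for gene lengths, gene types and overlaps only.

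Since a TPM value is a number of reads divided by a length and multiplied by a constant of the library, whole reads were recovered. The constant was found from genes whose GENCODE 29 exon length gave whole reads. With a tolerance of 0.01 reads in all 6 libraries, 9115 of 14833 tested genes came out whole with that length, and the other 5718 with the smallest whole length that gave whole reads, 100% in all. On simulated reads of the same 14833 genes, 99.7% had every read count right. If all 6 read counts of a gene share a divisor, its recovered reads are too low by that factor. The recovered reads cover 99.9% of the TPM of each library, and 3 reads on a gene of 1 kb correspond to 0.335 to 0.401 TPM. Floors cover counting error only. Within a group, pairs of libraries differed by more than counting error (chi-square per gene of 2.55 to 4.99 over genes with at least 10 reads in the pair), so no 2 libraries were counted as 1.

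Genes with at least 1 TPM in at least 3 of the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on log2(TPM + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of genes near or under 1 TPM. Fold values of the data without "log2" are ratios of mean TPM. The counts of genes changed at least 2-fold are the exception. They use the log2(TPM + 1) scale, which leaves out some genes with a TPM ratio above 2. The main design has no replicate block. For genes without reads in a group, the fold is a lower bound against 3 reads per library. Libraries of the 14833 genes were simulated with their own spread, with folds set on the log2(TPM + 1) scale rather than as TPM ratios. The fit for Dox against Ctrl recovered 28% of genes changed 1.2-fold, 66% at 1.5-fold, 96% at 2-fold and 98% at 4-fold (50 genes each). It made 2 false calls. Only 200 of the 14833 genes changed there, so the adjusted threshold was stricter than in the data, where 7959 genes were called.

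The 18 gene lists (362 genes, 265 tested) were fixed before the data were examined. The 17 described are YAP/TEAD target signature, Hippo pathway components, luminal and basal prostate epithelium, neuroendocrine, mesenchymal and EMT, G1/S and DNA replication, G2/M and mitosis, p53 targets, mitochondrially encoded, integrated stress response, immediate early and AP-1, actin cytoskeleton and SRF targets, NF-kB and inflammatory cytokines, cholesterol synthesis, interferon-stimulated genes, and stromal, endothelial and immune cells. Each was tested with limma's camera (preset correlation of 0.01, and again with an estimated correlation), adjusted over the 18 lists. No call of the preset test holds with an estimated correlation. Members were counted with p adjusted over all genes and over the list alone. Genes are named by a rule also fixed before: a set of 17 genes, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap (genes with only clone names passed over), and up to 4 changed members per list and direction. Some genes that meet these rules, 1 of the 18 lists and 1 list added after the data were seen are not reported here. Other list members are named as examples chosen after their values were seen.

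Alternatives were another pseudocount (0.1), no filter, a stricter filter (mean of at least 5 TPM), median-ratio rescaling, quantile normalization, leaving out mitochondrially encoded genes, no variance trend, a replicate block and leaving out each library. limma voom on the recovered reads and removal of each library's trend with gene length (loess, span 0.3) were added after the data were seen. A planned edgeR fit on recovered reads was not run, and voom on the same reads took its place. Figures were drawn with matplotlib 3.10.9.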

Results

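RNA sequencing was carried out on C4-2 cells, a castration-resistant human prostate cancer line derived from LNCaP. The cells carried Tet-O-YAP5SA, a doxycycline-inducible form of the transcriptional coactivator YAP1 in which the serines phosphorylated by the LATS kinases are replaced by alanine. The design has 3 libraries from cells without doxycycline (Ctrl) and 3 libraries from cells given doxycycline for 24 hours (Dox). The labels give the dose as 0.2 mg/ml, which is high for an inducible line, so its unit is in doubt and may be µg/ml. The comparison asks which transcripts change when active YAP1 is switched on. The table lists 26819 genes with levels in TPM (reads divided by gene length and scaled to the same total in every library), of which 14833 reached 1 TPM in at least 3 libraries and were tested. Reads recovered from the values came to 28787188, 27682447 and 27574083 in the Ctrl libraries and to 24941836, 27886782 and 29239717 in the Dox libraries. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical. The design has no cells without the transgene that received doxycycline, so an effect of the drug itself is part of every difference given here.

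YAP1 (ENSG00000137693.9) rose from 56.8 ± 3.72 TPM in Ctrl to 269 ± 6.92 TPM in Dox (SD, n = 3), a 4.74-fold higher level. The log2 fold change was 2.23 ± 0.05 (SE, limma adjusted p = 6.2e-08). The value is for the whole gene and does not separate transgene from endogenous transcripts. The 2 genes most used as YAP readouts, which encode secreted matricellular proteins, rose by far more. CTGF (CCN2, ENSG00000118523.5) went from 0.350 ± 0.140 to 398 ± 13.1 TPM, a log2 fold change of 8.21 ± 0.08. CYR61 (CCN1, ENSG00000142871.11) rose 221-fold to 2648 ± 46.2 TPM (log2 fold change 7.67 ± 0.04). ANKRD1, a transcriptional cofactor of stretched muscle, had no reads in any Ctrl library and 19.7 ± 3.49 TPM in Dox, at least 112-fold higher against a floor of 3 reads per library.

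**Figure D1:**
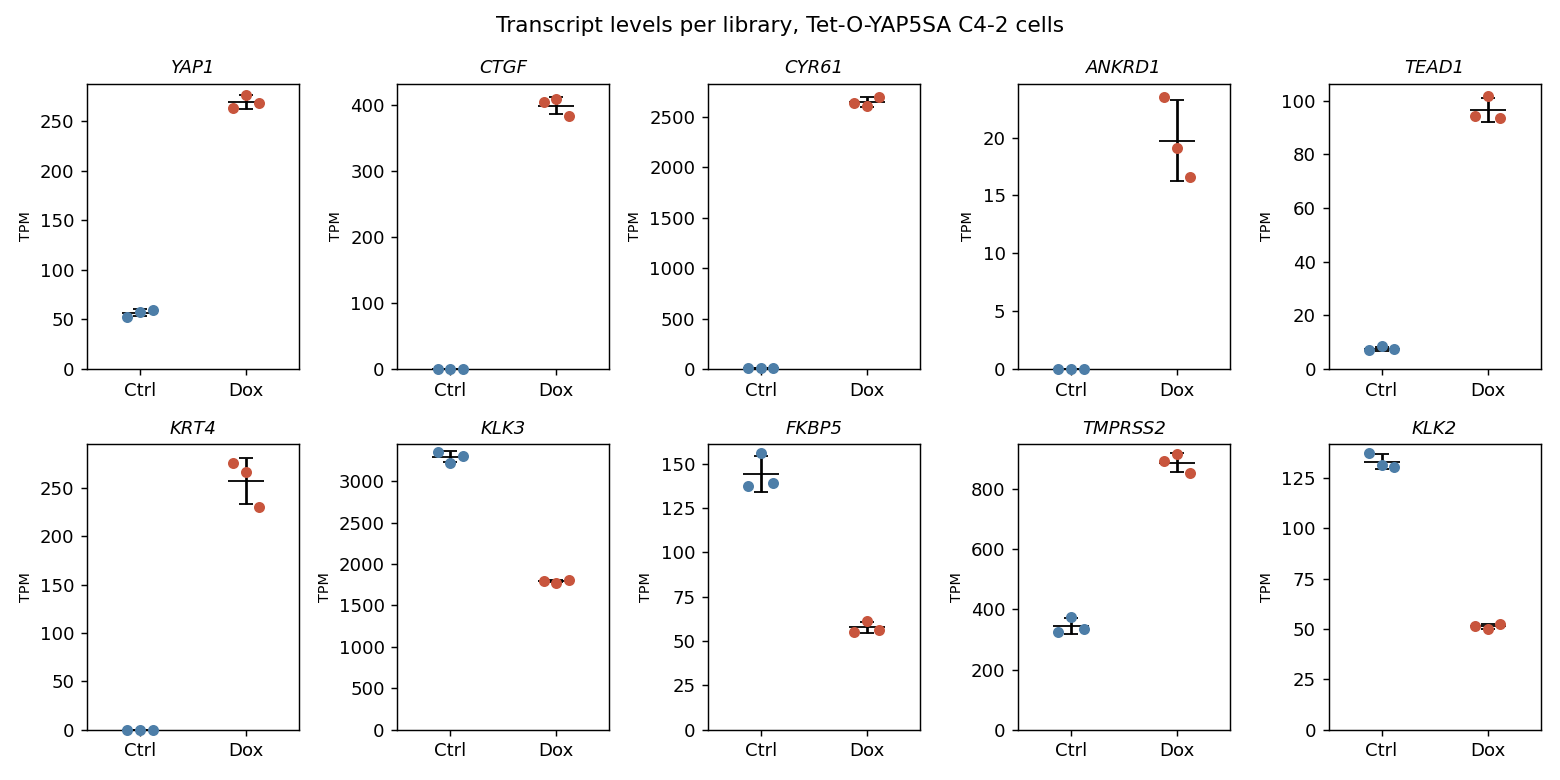
TPM (vertical axes, from 0) of 10 genes in each of the 3 Ctrl and 3 Dox libraries (points), with the group mean (horizontal bar) and SD (error bar). The groups do not overlap in any panel, and FKBP5 falls from 144 to 57.7 TPM while TMPRSS2 rises from 344 to 888 TPM.

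At a limma adjusted p under 0.05, 7959 genes changed, 53.7% of those tested. Of these, 5319 were higher and 2640 lower with doxycycline, and 726 had a log2 fold change of at least 1 in size on the log2(TPM + 1) scale, 604 upwards and 122 downwards. A size of at least 2 on that scale was found in 133 rising and 4 falling genes. The Ctrl and Dox libraries did not overlap for 9182 genes (61.9%), where chance gives 10%. Most changes were small, with a median absolute log2 fold change of 0.38 among the changed genes. The split into higher and lower genes depends on how the libraries are scaled to each other: 66.8% of the changed genes were higher on the deposited scale, 50.1% (3964 higher, 3948 lower) after median-ratio rescaling and 44.9% (3536 higher, 4348 lower) after quantile normalization. The median log2 fold change of all tested genes was 0.10 as deposited, and quantile normalization moved it by -0.13. Small changes are therefore to be read against that median. The camera tests of gene lists compare a list with all other tested genes.

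Besides CTGF and CYR61, the largest rises were those of KRT4, RASL11A, RPL39P5, AMOTL2, ANKRD2, ANKRD1, EDN1 and RBP2. KRT4, a keratin of the stratified mucosal epithelium, went from 0.0356 ± 0.0355 to 257 ± 23.6 TPM (log2 fold change 7.96 ± 0.08). RASL11A, a small GTPase of the Ras family, rose 37.1-fold to 286 ± 10.8 TPM. AMOTL2, a junction protein that binds YAP1, rose 27.8-fold to 214 ± 12.4 TPM. The pseudogene RPL39P5 rose to 301 ± 10.1 TPM, but it overlaps AMOTL2 on the same strand in GENCODE 29, so its reads cannot be assigned with certainty. ANKRD2, a relative of ANKRD1, rose 45.6-fold to 46.5 ± 1.27 TPM, and EDN1, which encodes the vasoconstrictor peptide endothelin-1, reached 25.4 ± 2.04 TPM from 0.376 ± 0.188 TPM. RBP2, a cellular retinol-binding protein, had no reads in Ctrl and was at least 43.6-fold higher in Dox against 3 reads per library.

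Among the largest falls were those of FOS, ANKRD37, CHAC1, TM4SF1, PCAT1, MIR4292, MIR3621, CXCL13 and DDIT3. FOS, a subunit of the AP-1 transcription factor, fell from 89.9 ± 4.64 to 17.8 ± 2.27 TPM (5.04-fold lower). ANKRD37, a gene raised by hypoxia, fell from 219 ± 14.2 to 50.4 ± 2.36 TPM. CHAC1, a glutathione-degrading enzyme induced by ATF4, fell 4.36-fold to 9.72 ± 0.866 TPM, and DDIT3, the stress transcription factor CHOP, fell 3.23-fold to 62.4 ± 7.20 TPM. The membrane protein gene TM4SF1 was 3.95-fold lower and the chemokine gene CXCL13 was 7.31-fold lower. The non-coding transcript PCAT1 fell from 10.5 ± 0.531 to 2.37 ± 1.05 TPM. It is annotated as antisense, and the strand setting of the counting is not given in the sources used here. MIR4292 and MIR3621 lie within RABL6 and LRRC26, so their values, 12.8 ± 5.58 to 2.96 ± 1.85 TPM and 3.63 ± 0.731 to 0.446 ± 0.772 TPM, may hold reads of those genes. At lengths of 67 and 85 bases these values also rest on few reads in each library, and MIR3621 was at 0 TPM in Dox 1 and Dox 2. Both falls are therefore close to the floor and their sizes are uncertain.

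**Figure D2:**
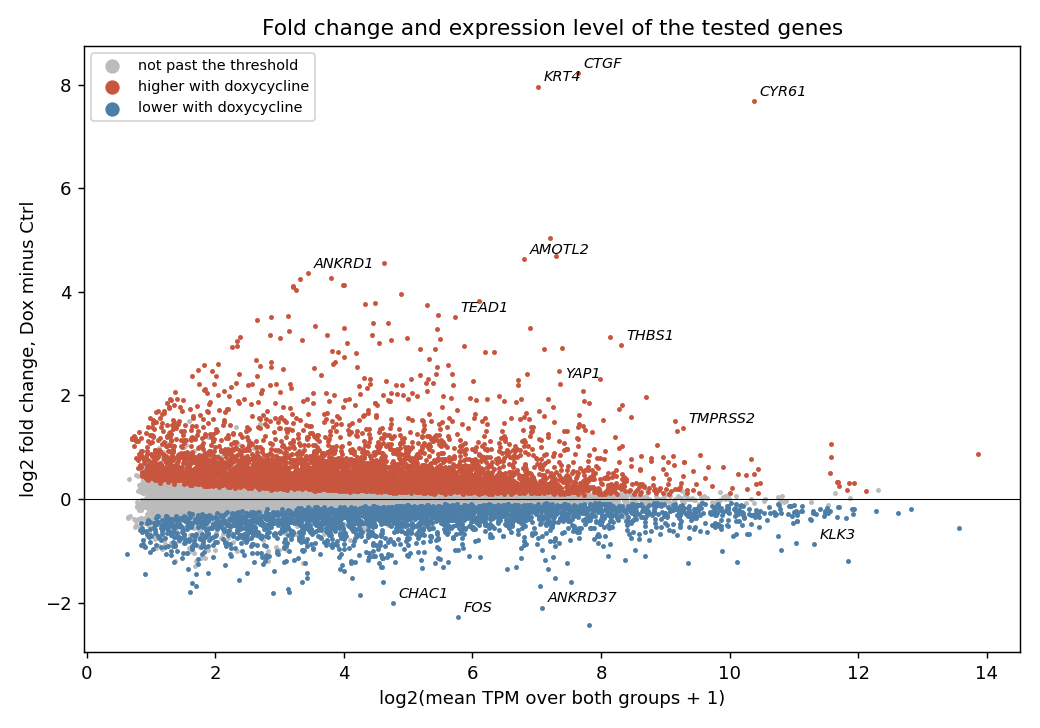
Log2 fold change (Dox minus Ctrl, on log2(TPM + 1)) of the 14833 tested genes against their log2(mean TPM + 1). Red points are the 5319 genes higher with doxycycline, blue points the 2640 lower genes and grey points genes not past the threshold; CTGF, KRT4 and CYR61 stand above a log2 fold change of 7.

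Among 16 tested genes of the published YAP/TEAD target signature, 13 rose, 2 fell and 1 did not pass the test. CTGF, CYR61, AMOTL2 and ANKRD1 rose most. CRIM1, a transmembrane regulator of growth factors, went from 3.51 ± 0.412 to 30.8 ± 1.48 TPM, and IGFBP3, which binds insulin-like growth factors, from 5.27 ± 0.0524 to 18.5 ± 0.472 TPM. GADD45A and NUAK2 were the members that fell, by 0.25 and 0.22 on the log2 scale, and the call of NUAK2 is lost without the filter on low values (adjusted p = 0.062) and without Ctrl replicate 1 (adjusted p = 0.092), Ctrl replicate 2 (0.087), or Dox replicate 1 (0.097), 2 (0.056) or 3 (0.056). The list stood above the other genes (limma camera, preset correlation of 0.01, adjusted p = 7.9e-06), with adjusted p = 0.41 with an estimated correlation. Adjusted over the list alone, the counts were again 13 higher and 2 lower.

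Of 25 tested Hippo pathway components, 19 rose and 2 fell (17 and 2 after median-ratio rescaling, 16 and 2 after quantile normalization). YAP1, the gene of the transgene itself, is among the 19 and is part of the list test. TEAD1, a DNA-binding partner of YAP1, rose 12.7-fold to 96.5 ± 4.50 TPM, and TEAD4 rose 2.99-fold to 48.4 ± 1.17 TPM. TEAD2 and TEAD3 had log2 fold changes of -0.07 ± 0.10 and -0.02 ± 0.08 and did not pass the test. VGLL1, a TEAD cofactor, went from 0.0254 ± 0.0441 to 16.5 ± 0.814 TPM. The YAP1 paralog WWTR1 (TAZ) stayed low, at 0.284 ± 0.0549 and 2.45 ± 0.0778 TPM, and rose. Other members that rose were the phosphatase PTPN14 (7.73-fold), the kinase LATS2 4.16-fold from 17.7 ± 0.825 to 73.4 ± 4.20 TPM, and the scaffolds WWC1 (79.4 ± 4.01 to 226 ± 7.83 TPM) and NF2 (29.1 ± 2.75 to 61.3 ± 2.76 TPM). The kinase LATS1 fell by 0.25 and FRMD6 by 0.35 on the log2 scale. The call of FRMD6 is lost without Ctrl replicate 1 (adjusted p = 0.057), Ctrl replicate 3 (0.085) or Dox replicate 1 (0.073). The list was higher as a whole (camera adjusted p = 9.3e-06; adjusted p = 0.41 with an estimated correlation), and adjusted over the list alone 19 members were higher and 2 lower. AMOTL2, LATS2 and PTPN14 also belong to the YAP/TEAD signature.

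Among the genes fixed before the data were seen, KLK3, which encodes prostate-specific antigen, fell from 3297 ± 69.6 to 1795 ± 17.1 TPM (1.84-fold lower, log2 fold change -0.88 ± 0.03). KLK2 fell 2.59-fold to 51.3 ± 1.19 TPM and FKBP5, a steroid receptor co-chaperone, from 144 ± 10.1 to 57.7 ± 3.22 TPM. TMPRSS2, a membrane serine protease, rose 2.58-fold from 344 ± 25.7 to 888 ± 31.1 TPM.

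The luminal prostate epithelium markers were divided, with 9 of 18 higher and 7 lower (7 and 8 after median-ratio rescaling, 10 and 8 after quantile normalization). KLK3, MSMB (log2 fold change -0.92 ± 0.11) and ACPP were among those that fell. FOXA1, the pioneer factor of the luminal lineage, rose 1.70-fold to 72.0 ± 4.82 TPM, GRHL2 1.56-fold and STEAP2 1.57-fold, and the keratins KRT8 and KRT18 rose to 582 ± 21.5 and 716 ± 4.01 TPM from 473 ± 7.22 and 523 ± 10.2 TPM. The median of the list was 0.10 and its mean -0.11, and camera gave a downward direction that did not pass (adjusted p = 0.50). Only 7 of 18 basal epithelium markers were expressed enough to test: the integrins ITGB4 (6.19 ± 0.193 to 16.0 ± 0.697 TPM) and ITGA3 (2.78 ± 0.280 to 6.94 ± 0.212 TPM) and the laminin LAMA3 rose, and ITGA6 fell from 21.8 ± 1.48 to 14.3 ± 0.184 TPM (camera adjusted p = 0.50). KRT14 was at 1.48 ± 0.175 and 1.44 ± 0.290 TPM. Of the neuroendocrine markers 3 of 20 were tested, and DLL3 (22.7 ± 1.07 to 14.3 ± 0.903 TPM) and ENO2 (109 ± 9.19 to 88.2 ± 5.41 TPM) fell (camera adjusted p = 0.10). Of 18 markers of stromal, endothelial and immune cells, 2 were tested: VWF rose from 1.25 ± 0.116 to 3.74 ± 0.226 TPM and CD68 fell from 20.2 ± 0.996 to 9.86 ± 0.508 TPM (camera adjusted p = 0.60, direction down, list median 0.05). Adjusted over the list alone, these 4 lists had the same counts.

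Genes of the actin cytoskeleton and targets of SRF rose in 12 of 16 cases, and none fell. MYL9, the regulatory light chain of non-muscle myosin, rose 3.96-fold to 98.1 ± 3.80 TPM and the heavy chain MYH9 3.02-fold to 532 ± 39.8 TPM. The crosslinkers FLNA and ACTN4 rose 2.51-fold and 2.31-fold. Beta-actin (ACTB) rose from 2203 ± 33.2 to 3889 ± 81.7 TPM, whereas gamma-actin (ACTG1) had a log2 fold change of -0.04 ± 0.03, did not pass the test; it is called lower after median-ratio rescaling (-0.15) and higher after quantile normalization (0.17). SRF itself was at 26.9 ± 3.41 and 30.0 ± 1.30 TPM. The list was higher (camera adjusted p = 4.6e-05; adjusted p = 0.41 with an estimated correlation), with 12 members higher when adjusted over the list alone.

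Genes of the integrated stress response, the program run by the transcription factor ATF4, fell in 16 of 20 cases and rose in 2. ATF4 itself went from 426 ± 13.2 to 266 ± 9.80 TPM (log2 fold change -0.68 ± 0.04). DDIT4, an inhibitor of mTORC1 signalling, fell 2.28-fold from 5086 ± 143 to 2228 ± 160 TPM, and SESN2 fell 2.25-fold. PSAT1 fell from 245 ± 10.3 to 158 ± 2.18 TPM, PHGDH from 258 ± 4.35 to 194 ± 3.82 TPM and ASNS from 113 ± 3.75 to 85.1 ± 6.67 TPM. The mitochondrial folate enzyme MTHFD2 rose 1.32-fold and ATF5 1.39-fold. ATF3 did not pass the test (191 ± 4.52 and 205 ± 12.2 TPM). The list lay below the other genes (camera adjusted p = 4.7e-07; adjusted p = 0.41 with an estimated correlation), and adjusted over the list alone the counts were 2 higher and 16 lower.

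Immediate early and AP-1 genes were mixed, with 7 of 14 lower and 4 higher (8 lower and 4 higher when adjusted over the list alone). FOS, DUSP5 (3.31-fold lower), IER3 (2.18-fold lower) and KLF6 (2.01-fold lower) fell. JUNB fell from 311 ± 13.4 to 190 ± 33.6 TPM and JUND from 545 ± 30.9 to 313 ± 21.6 TPM. MYC rose 2.20-fold from 83.4 ± 4.23 to 184 ± 8.63 TPM, and the phosphatase gene DUSP1 rose 1.93-fold. The list's call downwards (camera adjusted p = 0.034) ends with an estimated correlation (adjusted p = 0.60), after median-ratio rescaling (0.11), and without Dox replicate 1 (0.053) or Dox replicate 2 (0.058).

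Of 20 G1/S and DNA replication genes 3 rose, 3 fell and 14 did not pass the test, and of 22 G2/M and mitosis genes 6 rose and 6 fell, the same when adjusted over each list alone. Among the members, CCNE2 rose 1.49-fold and CDK1 1.45-fold to 819 ± 49.5 TPM. The licensing factor CDT1 fell 1.79-fold to 21.6 ± 0.590 TPM and BIRC5 1.19-fold. CCND1, the G1 cyclin, which is on neither list, rose 1.52-fold to 299 ± 20.4 TPM. MKI67 had a log2 fold change of -0.07 ± 0.06 and did not pass the test; it is called lower after median-ratio rescaling (-0.18) and after quantile normalization (-0.20). The G1/S list had a median of 0.06 and a mean of 0.01 with a camera direction of down (adjusted p = 0.59), and the G2/M list a median of -0.06 and a mean of 0.01 with a direction of down (adjusted p = 0.23). With median-ratio rescaling 2 G1/S genes were higher and 8 lower, and 3 G2/M genes were higher and 13 lower (2 and 6, and 4 and 13, after quantile normalization); under median-ratio rescaling CCNB2 and RRM2 no longer passed the test.

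The p53 targets were divided, with 7 of 20 higher and 8 lower, also when adjusted over the list alone, but 5 higher and 10 lower after median-ratio rescaling and 4 higher and 10 lower after quantile normalization (camera adjusted p = 0.14, direction down). PMAIP1, which encodes the pro-apoptotic protein NOXA, fell 3.31-fold to 4.53 ± 0.112 TPM, the cell cycle inhibitor CDKN1A fell 1.82-fold from 209 ± 14.1 to 115 ± 3.31 TPM and SESN1 fell 2.00-fold. PLK2 rose 9.81-fold to 23.8 ± 1.72 TPM and TP53INP1 1.75-fold. MDM2 was at 31.9 ± 2.07 and 32.7 ± 2.14 TPM. Of 8 tested mesenchymal and EMT genes, 3 rose and 3 fell, as they did adjusted over the list alone (1 and 4 after median-ratio rescaling, 2 and 4 after quantile normalization). THBS1, the matricellular protein thrombospondin-1, rose 7.93-fold from 71.3 ± 5.45 to 565 ± 22.5 TPM, whereas VIM fell from 47.3 ± 1.18 to 32.1 ± 2.56 TPM, SNAI1 from 17.9 ± 0.749 to 10.7 ± 0.505 TPM and LOX from 19.2 ± 0.779 to 10.8 ± 0.228 TPM. The small rises of FN1 and COL1A1 (1.17-fold and 1.22-fold) do not pass after median-ratio rescaling (COL1A1 adjusted p = 0.075) or with the length trend removed (FN1 adjusted p = 0.19, COL1A1 0.087). The call of COL1A1 is also lost after quantile normalization (limma adjusted p = 0.37) and without Ctrl replicate 3 (0.061) or Dox replicate 3 (0.052). The list's median was -0.07 and its mean 0.16, with a camera direction of down (adjusted p = 0.44).

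Cholesterol synthesis genes were split, 8 of 19 higher and 8 lower, also adjusted over the list alone, but 5 higher and 10 lower after median-ratio rescaling and 6 higher and 10 lower after quantile normalization (camera adjusted p = 0.061, direction down). INSIG1, the sterol sensor that retains SREBP, fell 2.32-fold from 1558 ± 30.3 to 670 ± 8.93 TPM. IDI1 fell 1.97-fold. HMGCS1 rose 1.55-fold. Of 11 NF-kB and inflammatory genes 3 rose and 3 fell, the same adjusted over the list alone (3 and 5 after either rescaling). The chemokine gene CCL2 rose 8.18-fold to 8.34 ± 0.698 TPM and NFKB2 1.55-fold, and the inhibitor NFKBIA fell 1.81-fold to 175 ± 7.04 TPM. That list's median was -0.08 and its mean 0.13, with a direction of down (camera adjusted p = 0.50). Of 15 interferon-stimulated genes 4 rose and 5 fell, also adjusted over the list alone, while 3 rose and 7 fell after median-ratio rescaling and 3 rose and 9 fell after quantile normalization (camera adjusted p = 0.32, direction down). OAS1 fell from 1.32 ± 0.0680 to 0.350 ± 0.0996 TPM.

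Of the 13 mitochondrially encoded protein genes 8 rose and none fell (9 higher when adjusted over the list alone). MT-CYB rose 1.40-fold from 1107 ± 95.3 to 1547 ± 71.1 TPM, and MT-ATP6, MT-CO3 and MT-CO2 rose 1.25-fold, 1.23-fold and 1.23-fold. The number of rises depends on the scaling: 1 of the 13 passed after median-ratio rescaling, 12 after quantile normalization and 13 with the length trend removed. MT-CYB is called higher under each. The list did not pass (camera adjusted p = 0.071; 0.0016 without Ctrl replicate 1). Mitochondrially encoded transcripts took 3.29% to 3.92% of the TPM in the Ctrl libraries and 3.91% to 4.11% in the Dox libraries.

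**Figure D3:**
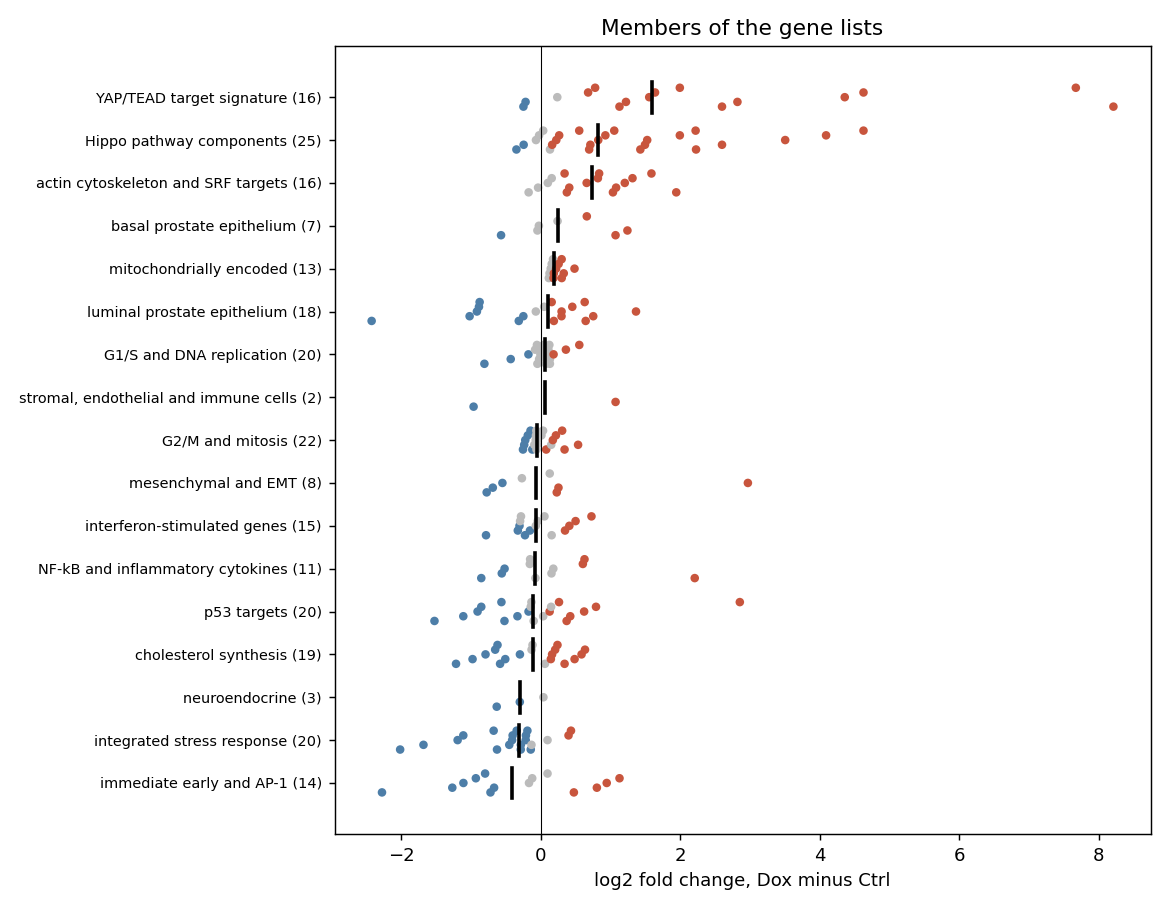
Log2 fold change (Dox minus Ctrl) of each tested member of 17 gene lists, with the number of tested members in brackets. Red and blue points are members past the threshold, higher and lower, grey points are not past it, and the black bar is the list's median, highest in the YAP/TEAD target signature and lowest, at -0.42, in the immediate early and AP-1 list.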

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

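Fits with limma voom on recovered reads and with the length trend removed were chosen after the data were seen; the other alternatives were planned, and the planned edgeR fit was not run. Over the 15 alternatives other than quantile normalization, the counts of changed, higher, lower and at least 2-fold changed genes stayed within 1.5 times of the reported ones. Median-ratio rescaling came close to that bound, with 3948 lower genes against 2640, and 50.1% of its changed genes were higher. Quantile normalization gave 3536 higher and 4348 lower genes, against 5319 and 2640, and moved the median log2 fold change of all genes by -0.13; 7 genes were called in opposite directions. Leaving out 1 library gave 6752 to 7589 changed genes and shared 83.2% to 90.5% of the calls with their direction. voom called 8511 genes. The YAP1 log2 fold change lay between 2.12 and 2.27 over all 16 alternatives. Of 122 named genes, 13 lost their call under 1 or more of the alternatives in which they were tested and none reversed. Most of the 122 were named because they were called with large changes, so few losses and reversals are in part built in. The stricter filter kept 104 of the 122 and leaving out mitochondrially encoded genes 118.

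The values show no clear pairing by replicate number, and the labels do not say whether the numbers mark shared cultures. Deviations from the group means correlated by -0.01, 0.06 and 0.00 between same-numbered libraries, and libraries of Ctrl 1 and 3 correlated best with another number (0.04 and 0.03). With 3 libraries per group, such correlations cannot exclude pairing. With the number as a replicate block, 7841 genes changed, 5223 higher and 2618 lower, 729 at least 2-fold, the YAP1 log2 fold change was 2.23, and 6 lists passed.

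For the lists, an estimated correlation ended the calls of the YAP/TEAD target signature, Hippo pathway components, integrated stress response and actin cytoskeleton and SRF targets (each adjusted p = 0.4122, and 0.2849 with the length trend removed as well) and of immediate early and AP-1 (0.5974, and 0.6942). The estimate rests on 4 residual degrees of freedom. fry, which asks only whether members move one way and does not compare them with other genes, passed each of the lists just named. It was run on the deposited scale only, where the median log2 fold change of all tested genes was 0.10, so its calls depend on that scale. Its adjusted p for them ran from 5.0e-06 (YAP/TEAD target signature) to 0.0182 (immediate early and AP-1). It also passed luminal prostate epithelium (0.0417, down), basal prostate epithelium (0.00235, up), neuroendocrine (0.00235, down) and cholesterol synthesis (0.000423, down). Luminal prostate epithelium passed downwards although 9 members were higher and 7 lower. With the length trend removed camera passed mitochondrially encoded (0.0110) and cholesterol synthesis (0.0345), and median-ratio rescaling lost immediate early and AP-1 (0.109). Leaving out 1 library gave adjusted p of 0.00616 to 0.0575 for immediate early and AP-1 and 0.00155 to 0.175 for mitochondrially encoded. The cause of these changes was not tested. A 1.2-fold change on the log2(TPM + 1) scale was mostly missed in simulation, where only 200 of the 14833 genes changed. With 7959 genes called, the adjusted threshold was less strict in the data, so that recovery does not carry over.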

Other observations

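The tests of the lists described first and of 1 of the explanations (the slopes of single libraries with gene length) were chosen only after the result was seen. Most tested genes of the hypoxia response fell. Of 20 tested members, leaving out ANKRD37, DDIT4, STC1 and CA12, whose falls prompted the list, 17 fell, 2 rose and 1 did not pass the test. The angiogenic factor VEGFA went from 42.1 ± 0.655 to 19.4 ± 2.13 TPM (SD, n = 3). The glycolytic enzymes ALDOA (2146 ± 70.4 to 1309 ± 99.9 TPM), LDHA (2344 ± 78.7 to 1705 ± 39.7 TPM) and HK2 (87.6 ± 1.61 to 57.1 ± 4.64 TPM), the glucose transporter SLC2A1 (log2 fold change -0.51 ± 0.05) and PDK1 (41.5 ± 1.65 to 25.8 ± 0.654 TPM) fell as well. EGLN3 (log2 fold change 0.83 ± 0.04) and NDRG1 (316 ± 2.30 to 465 ± 28.8 TPM) rose. The hypothesis that hypoxia response genes fall as a group met its prediction with the preset correlation (limma camera p = 9.4e-10). The members tested were measured in the same libraries as the falls that prompted the list and may vary with them, so this is not an independent test. With an estimated correlation p was 0.044, not adjusted, which does not pass once adjusted over the lists added after the data were seen. Oxygen supply and cell density were not measured, so a difference in culture density may be as good an account of this as the transgene.

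The rises of KRT4, KRT80 (2.05 to 40.7 TPM), TGM1 (0.714 to 29.1 TPM), PI3 (8.42 to 79.3 TPM) and CLDN1 (0.157 to 7.94 TPM) prompted a list of squamous epithelium genes. Its 14 other tested members went both ways, 7 higher and 6 lower, among them SFN (3.54 to 11.6 TPM) and PPL (6.20 to 15.8 TPM) upwards and DSG2 (178 to 121 TPM) and CSTA (27.1 to 16.2 TPM) downwards. The prediction of a common rise was not met: the limma camera p was 0.36.

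Fold changes rose with exon length over 11853 protein-coding genes (Spearman 0.20, across genes, which are not independent replicates). The median log2 fold change was -0.02 in the shortest length decile and 0.22 in the longest. The slopes of single libraries were taken on deviations from each gene's mean over the 6 libraries, so only their differences carry meaning, not their signs. They lay between -0.05 and -0.02 log2 units per doubling of length in Ctrl and between 0.02 and 0.05 in Dox. The gap of 0.0398 between the groups was wider than the widest range within a group (0.0350). Whether long genes rose or short genes fell depends on the scaling, since the median of all tested genes was 0.10 on the deposited scale. A length bias of the libraries and a response of long or of short genes cannot be told apart, because the library sets coincide with the groups. The trend does not make the calls: with it removed, 90.9% of the called genes were still called in the same direction.

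Of 20 tested genes of the integrated stress response 16 fell and 2 rose, and the call of the list is lost with an estimated correlation (camera adjusted p = 0.41, and 0.28 with the length trend removed as well). A length bias was argued against as the whole cause, since 15 of the 16 falling members still fell with the trend removed. The design has no doxycycline without the transgene, so effects of the drug stay open, as does the biological difference the design names, which was not tested apart from it.

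With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split was the 1 split with the largest count in each case. It gave 7959 changed genes and the highest other split 1, 5319 higher and 2640 lower genes against at most 1, 726 genes changed at least 2-fold against 1, and 6 lists against 4. Every other split mixes Ctrl and Dox libraries on both sides, so a difference between the groups adds to its spread. Low gene counts in those splits are therefore built in and do not show what would arise without a treatment effect.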
